A study of Mus musculus with 2 samples.

How the data were processed

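CD4 T cells of brown adipose tissue (BAT), subcutaneous adipose tissue (SAT), visceral adipose tissue (VAT) and spleen of 8-week-old male wild-type C57BL/6J mice were measured by droplet-based 3-prime RNA sequencing with hashtag antibodies. Per the labels, live cells positive for the T cell receptor beta chain, CD3 and CD4 were sorted, fat was minced and digested with collagenase, and spleen was only dissociated mechanically. The labels name 2 libraries, 1 per experiment, with 8 hashed samples each, that is 2 biological duplicates of each tissue per experiment. The hashed samples of experiment 1 are called replicates 1 and 2 here, and those of experiment 2 replicates 3 and 4. The labels do not say whether duplicates of an experiment are separate animals, or which visceral depot was taken.

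The deposited files are 1 sparse matrix per library, in raw UMI counts per cell barcode for 55487 genes and raw hashtag counts for 15 hashtags. Cell Ranger 6.1.0 wrote them, per the file headers, with the genome build mm10. The authors also name bcl2fastq and Seurat, whose versions and settings are not given in the sources used here. Every count is a whole number, and no gene count had been scaled. Gene symbols were taken from the matrices, where 114 symbols stand for more than 1 gene and were kept apart by their IDs. Coordinates came from GENCODE vM21 for the same build, in which 54349 of the gene IDs were found.

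Cells were kept with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs. Of 4485 and 12239 barcodes, 3985 and 9004 passed. Scrublet, as run by scanpy 1.11.5 with an expected rate of 0.06 and 30 components, called 0 doublets in both libraries, so that its alternative is void. Hashtags of more than 1 sample were found on 333 and 1384 cells. Those of library 1 had a median of 11796 UMIs against 5969 in cells of 1 sample, and those of library 2 had 2839.5 against 4591 and included 69.3% of its erythroid-like cells. Hashtag counts were log-transformed, freed of the trend with the background and expressed in robust standard deviations of each hashtag's background. A mixture of a negative state, 8 single-sample states and 28 pair states was fitted by expectation-maximisation, and a cell was given to a sample at a posterior above 0.95. Single-sample calls numbered 3345 and 6632, multiplets 8.36% and 15.4% of cells, and 307 and 988 cells stayed unresolved. Some hashtags were weak, that of SAT replicate 1 with a separation of 2.03 robust standard deviations and that of BAT replicate 4 with 2.64. In simulated hashtag data with a weak tag 67.2% of its cells were recovered and 99.0% of its calls were correct, and at least 93.9% were recovered for the other tags. The simulated levels were set by hand and not matched to these weak hashtags, so they do not give the error of their calls. In the data 0 cells were called negative, and both weak hashtags had the largest fitted share of their library, 15.5% and 12.6%. A stricter setting asked for a posterior above 0.99 and a margin of 2 robust standard deviations, which kept 57 of 477 cells of SAT replicate 1 and 448 of 747 of BAT replicate 4. The 7 hashtags outside the labels held 0.0856% and 0.0964% of hashtag counts and were not used.

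Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without T cell receptor genes gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1.0 (scanpy, igraph 0.11.9). A cluster was named after a class when at least 3 of its markers were higher by 0.5 log2 units and found in at least 5% of cells, by its leading genes where several classes passed. The names are written with "-like", since no protein was measured. Clusters of B cells, myeloid cells, fibroblasts and erythroid cells were left out, which removed 254 and 697 cells and left 3731 and 8307 alpha-beta T cells. A cluster of 17 and 1335 cells with few UMIs, median 1592 in library 2, stayed in. Shares of cells carry exact (Clopper-Pearson) 95% intervals in the tables, for counting error only.

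A cell was called positive for Foxp3, Il1rl1, Cxcr3 or Cxcr6 with at least 1 UMI of the gene and zero without any. Raw counts were summed per library and class, or per hashed sample, for samples of at least 20 cells, so that BAT entered the comparisons of Foxp3-positive cells with replicates 1 and 4 only. Sums of Foxp3-positive cells held 101829 to 384932 UMIs per hashed sample, and those of Foxp3-zero cells 1848236 to 4743098. In the comparisons of classes within libraries they held 396521 to 2779446 UMIs for Foxp3-positive classes and their subsets, and up to 36430662 for the others. Tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr with a minimum count of 10 and quasi-likelihood tests. The library was a term in the class comparisons, which had 4 sums and 1 residual degree of freedom, and the experiment was a term in the tissue comparisons, with all 4 tissues in 1 fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were taken from the fold change and its test statistic. Gene values are log2 fold changes and mean counts per 1000000 (CPM). On simulated counts of the same depth 87.9% of genes with 4-fold changes were recovered for Foxp3, 90.9% for Il1rl1, 93.9% for Cxcr3 and 95.5% for Cxcr6 classes, 90.9%, 89.4% and 86.4% for Foxp3-positive SAT against VAT, SAT against spleen and VAT against spleen, and at least 95.5% for Foxp3-zero tissues. With 2-fold changes the values were 59.7%, 49.3%, 58.2% and 74.6% for the classes. They were 55.2%, 50.8% and 53.7% for the Foxp3-positive tissues named, and at least 77.6% for Foxp3-zero tissues. In these simulated counts up to 8.99% of the calls in a comparison were false. The simulation drew on the dispersions that the fits gave and held no effect of library or experiment. Its rates of recovery and of false calls may therefore be better than those in the data.

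Comparisons, gene lists and the rule for naming genes were fixed before the data were examined. Named genes are among the 15 highest and 10 lowest log2 fold changes of called genes with at least 20 CPM in the higher class and the same direction in both libraries or experiments, without the genes that split the classes, predicted genes, ribosomal and mitochondrial genes and T cell receptor variable segments, or they are members of a fixed list with the largest changes. Some genes are not reported here and remain in the lists and counts. The 19 lists are Treg core, adipose Treg, naive and recirculating, Th1, Th17, Th2, Tfh, immediate early and dissociation, T cell receptor activation and costimulation, interferon response, cell cycle, lipid metabolism, repair and effector products, migration and adhesion, costimulatory and inhibitory receptors, mitochondrially encoded, adipose tissue background, myeloid background and B cell background genes. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, with fry as a second set test, and list p-values were adjusted over the lists of a comparison. Shares per tissue were compared by 2-sided exact permutation of samples within experiments, 36 arrangements, adjusted over the 6 tissue pairs.

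The alternatives set beforehand were DESeq2 1.42.0, scaling by library size only, no filter, a stricter filter of 50 counts, at least 2 UMIs of the splitting gene, cells thinned to 1300 UMIs, no library or experiment term, other clusterings and cell filters, clusters in place of Foxp3, each sample left out and a stricter hashtag margin. Further ones were added after the data had been seen, such as cells without multiplets or without the low-UMI cluster, sums per hashed sample, samples of at least 10 cells, a block by replicate number, and tests of whether a tissue difference depends on Foxp3. Duplicates of 1 tissue differed by more than the counting noise of UMIs, with a chi-square per gene of 1.21 to 3.64. Differences between the cells of 1 sample can also give this, so it does not show separate animals. Deviations of samples with the same number in different tissues had correlations across genes of -0.17 to 0.04. The numbers were therefore not used to pair samples. T cell receptor sequences and the raw reads were not analysed here.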

Results

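Single-cell RNA counts were collected from CD4 T cells of 8-week-old male C57BL/6J mice, sorted from brown adipose tissue (BAT), subcutaneous adipose tissue (SAT), visceral adipose tissue (VAT) and spleen. The cells were stained with hashtag antibodies, pooled and run as 2 droplet libraries, 1 per experiment, with 8 hashed samples in each, so that each tissue had 4 hashed samples. The series concerns the regulatory T cells (Treg cells) of BAT and SAT, and the comparisons below ask how T cells with Foxp3 transcripts differed from the rest and how the tissues differed from one another. Library 1 held 29153747 gene UMIs in 4485 barcodes and library 2 held 43879975 in 12239. After the cell filter 3985 and 9004 cells remained, with medians of 6107 and 4306.5 UMIs and of 2034 and 1519 genes per cell. Hashtags placed 3345 and 6632 of them in 1 sample. Alpha-beta T cells numbered 3731 and 8307, of which 3170 and 6507 had a tissue. Cells assigned to a sample ran from 336 to 495 per sample in experiment 1, at median depths of 5350 to 6639 UMIs. In experiment 2 they ran from 706 to 997, at 4010 to 5048.5 UMIs. In each experiment the lowest median was in BAT and the highest in spleen. Fat was digested with collagenase and spleen was not, so a comparison of fat with spleen holds both differences. The duplicates of an experiment may not be separate animals, and the p-values of the tissue comparisons measure only the spread between these samples. In the class comparisons the spread was pooled over genes. Their p-values and standard errors hold little of a gene's own difference between the 2 libraries.

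Effector-like cells were common in SAT and VAT, and naive-like cells were most common in BAT and spleen. Clusters led by Cxcr6, Cxcr3, Ifng and Tbx21, genes of type 1 helper (Th1) cells, made up 36.1% ± 10.4 of CD4 T cells in SAT and 37.2% ± 9.20 in VAT, against 5.82% ± 1.97 in BAT and 1.44% ± 1.16 in spleen (mean ± SD, n = 4 hashed samples). Cells with the natural killer T (NKT) markers Klrb1c and Cd160 were most common in SAT, at 11% ± 2.8, against 4.34% ± 0.631 in VAT. Cells led by Tmem176a, Tmem176b and Ccr6, markers of Th17 cells, and Tfh-like cells with Pdcd1 and Slamf6 were most common in VAT, at 4.44% ± 1.32 and 9.3% ± 2.0, against 1.02% ± 0.403 and 4.80% ± 1.46 in SAT. Naive-like cells, which carried Igfbp4, Dapl1 and Ccr7, made up 55.7% ± 11.1 in BAT, 40% ± 7.2 in spleen, 22.2% ± 5.19 in VAT and 17.5% ± 4.24 in SAT. The BAT and spleen values have no order between them, because an unnamed cluster with Satb1 and Itm2a held a further 22.3% of BAT and 30.4% of spleen cells, and 35.4% ± 22.1 of BAT cells, 54.5% in experiment 1 and 16.4% in experiment 2, lay in a naive-like cluster led by Hspa1b, Hspa1a and Jun. Treg-like cells, led by Foxp3, Ikzf2 and Ctla4, made up 3.57% ± 0.784 in BAT, 9.31% ± 2.52 in SAT, 11% ± 1.8 in VAT and 11.6% ± 1.89 in spleen. Within experiments the Th1-like share of SAT exceeded that of spleen by 42.2 points in experiment 1 and 27.2 in experiment 2, and the NKT-like share of SAT exceeded that of VAT by 6.43 and 6.88 points. SAT differed from VAT by -3.34 and -3.50 points in the Th17-like share and by -3.36 and -5.69 in the Tfh-like share. Each of these 4 differences had the smallest p that a 2-sided exact permutation within experiments can give, 0.0556, so none could pass 5%. Adjusted over the 6 tissue pairs of its class it was 0.0667 for the Th1-like, NKT-like and Th17-like shares and 0.0833 for the Tfh-like share. At a coarser clustering the Th17-like and Tfh-like clusters were not found, Th1-effector-like cells made up 5.26% of spleen, and naive-like cells 80.4% of BAT and 78.0% of spleen. With components centred per library NKT-like cells made up 16.1% of SAT and 7.21% of VAT.

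**Figure D1:**
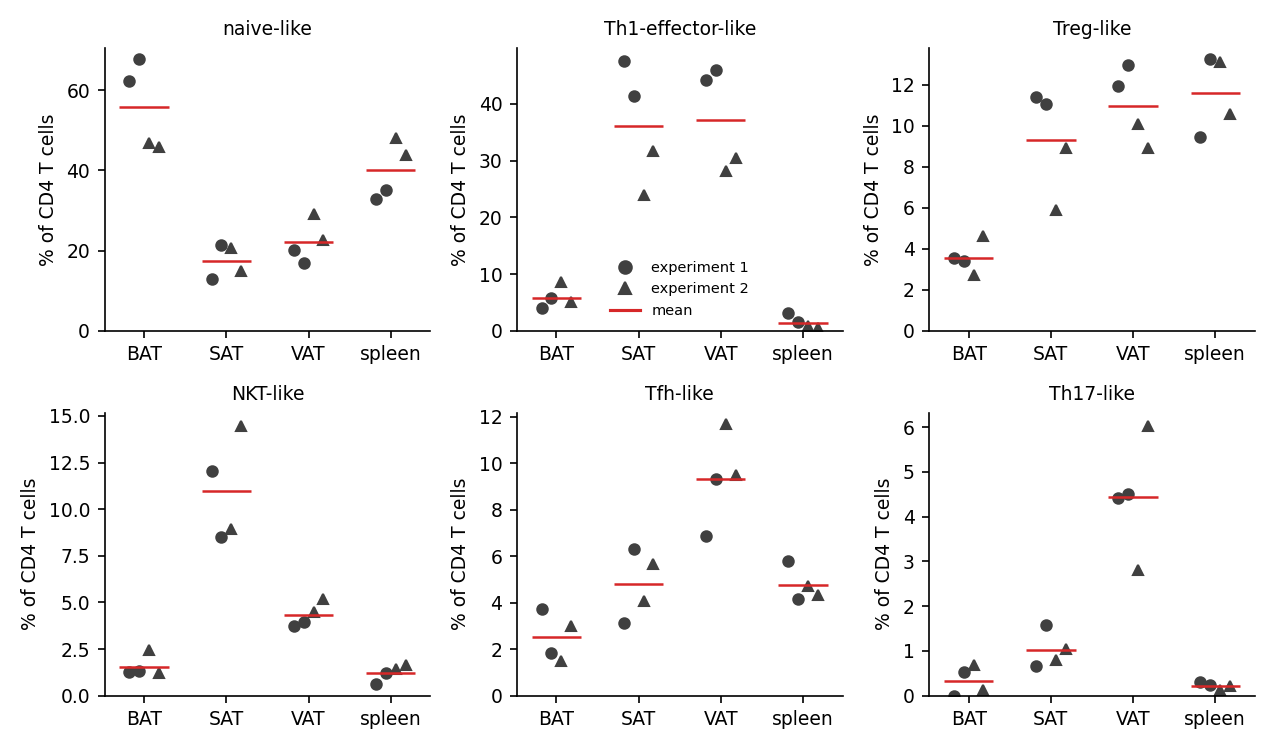
Share of CD4 T cells in each marker-named class (y axis, percent) by tissue (x axis); each point is 1 hashed sample, its shape gives the experiment, and the line is the mean of 4. Th1-effector-like cells averaged 36.1% in SAT and 37.2% in VAT against 1.44% in spleen.

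BAT held the smallest share of Foxp3-positive cells. Foxp3 encodes the transcription factor of Treg cells, and a UMI of it was found in 3.80% ± 1.60 of CD4 T cells of BAT, 7.93% ± 2.66 of SAT, 9.23% ± 2.59 of VAT and 8.27% ± 2.54 of spleen (mean ± SD, n = 4). The difference of BAT from SAT was -5.39 points in experiment 1 and -2.88 in experiment 2, from VAT -6.62 and -4.25, and from spleen -5.27 and -3.68. Each BAT difference had an exact permutation p of 0.0556, the smallest possible, and 0.111 after adjustment over 6 pairs. SAT, VAT and spleen did not differ by more than the spread between samples (exact permutation p 0.167 for SAT against VAT, 0.722 for SAT against spleen and 0.444 for VAT against spleen). BAT also had the fewest UMIs per cell. With T cells of at least 1300 UMIs thinned to that depth, and 3 and 601 shallower cells of libraries 1 and 2 left out, the shares were 1.64% ± 0.409 in BAT, 3.56% ± 1.25 in SAT, 4.59% ± 1.53 in VAT and 3.17% ± 0.814 in spleen, and BAT remained lowest.

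**Figure D2:**
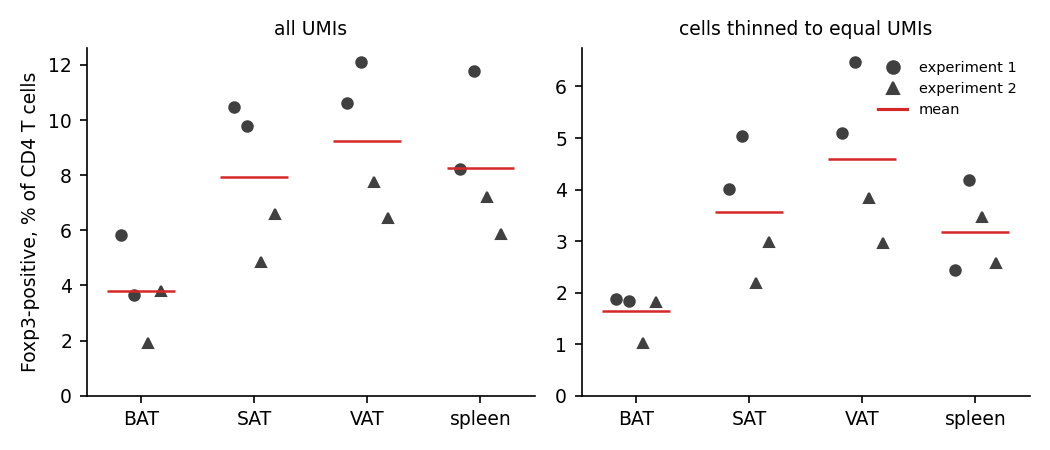
Share of CD4 T cells with at least 1 Foxp3 UMI (y axis, percent) by tissue (x axis), at full depth and after thinning of cells of at least 1300 UMIs to that depth; points are hashed samples, shapes give the experiment, and lines are means of 4. The mean of BAT was 3.80% at full depth against 7.93% in SAT.

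Foxp3-positive cells had more of the Treg core genes and of the repair products. Against T cells without a Foxp3 UMI they had more Il2ra and Ctla4, which encode the high-affinity IL-2 receptor chain and an inhibitory receptor, with log2 fold changes of 3.78 ± 0.10 and 3.67 ± 0.07 (± SE, n = 2 libraries). Areg, which encodes the tissue repair factor amphiregulin, rose by 4.12 ± 0.15, from 3.93 to 73.5 CPM (counts per 1000000), and the cytokine gene Il10 by 5.61 ± 0.36. The neutrophil chemokine gene Cxcl2 rose most among the named genes, by 7.74 ± 0.16, with 142 CPM against 0.624. Other genes with a high rise were Frmd5 at 5.64 ± 0.28, Ccr3 at 3.90 ± 0.25, Lrrc32 at 3.66 ± 0.25 and the transcription factor gene Ikzf2 at 3.58 ± 0.06. The cytotoxic gene Gzma fell by 3.75 ± 0.25, Xcl1 by 2.69 ± 0.12, Dapl1 by 2.06 ± 0.08, Ly6c2 by 1.82 ± 0.10 and Il2 by 1.76 ± 0.17. In library 2 alone, as log2 ratios of CPM + 1 with no test, Il10 rose by 2.97 and Gzma fell by 2.10. Areg rose by 4.81 in library 1 and by 2.85 in library 2 on that scale, further apart than its standard error tells. The classes were split by Foxp3, X:7573644-7595245 in mm10 (ENSMUSG00000039521.13, protein coding), which was left out of every test of this comparison.

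In the lists of genes, 17 of 18 Treg core genes were higher in Foxp3-positive cells, with a median log2 fold change of 2.59. Of 23 adipose Treg genes 20 were higher and 1 lower, and 10 of 11 repair products were higher, Ebi3 by 3.43 ± 0.33. All 13 naive and recirculating genes were lower, with Tcf7 at -1.17 ± 0.06 and Lef1 at -1.09 ± 0.06. Among 13 Th1 genes 8 were lower, with Ifng at -1.40 ± 0.10 and Ccl5 at -1.14 ± 0.05, and 2 were higher. Receptors for costimulation and inhibition were higher in 6 of 8 genes and lower in 1, with Tigit at 2.64 ± 0.32. Migration genes were higher in 11 of 19 and lower in 3, with Ccr6 at 2.71 ± 0.25. Immediate early and dissociation genes were higher in 11 of 16 and lower in 1, with Atf3 at 2.78 ± 0.36 and Nr4a1 at 1.43 ± 0.09. Adjusted over the list alone the counts were 17 higher for the Treg core, 20 higher and 2 lower for adipose Treg genes, 10 higher for repair products, 13 lower for naive genes, 2 higher and 11 lower for Th1 genes, 6 higher and 2 lower for receptors, 13 higher and 4 lower for migration, and 11 higher and 1 lower for immediate early genes. The preset-correlation camera test gave adjusted p-values of 5.9e-179, 1.9e-68, 8.0e-33, 1.4e-37, 4.2e-11, 2.0e-22, 6.5e-09 and 5.6e-16 for these lists in the same order. With an estimated correlation the adjusted p was 0.29 for all 8, an estimate that rests on 1 residual degree of freedom.

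Smaller movements were found in the other lists of this comparison. Of 4 Th17 genes 2 were higher (camera adjusted p = 0.019, and adjusted p = 0.36 with an estimated correlation). Lipid genes were higher in 4 of 14, with Plin2 at 1.10 ± 0.11 and Fabp5 at 1.08 ± 0.12 (adjusted p = 0.017 and 0.36). Mitochondrially encoded genes were lower in 8 of 11, with mt-Nd2 at -0.38 ± 0.05 (adjusted p = 4.4e-04 and 0.29). Of 8 Tfh genes 3 were higher and 2 lower, Izumo1r at 1.56 ± 0.07, with a median of 0.56 and a mean of -0.12 and a camera adjusted p of 4.6e-05, or 0.29 with an estimated correlation. T cell receptor activation genes went both ways, 5 of 13 higher and 5 lower, with Icos at 1.69 ± 0.08 and Cd40lg at -1.49 ± 0.08 (adjusted p = 0.96). The Th2 list had Gata3 higher at 0.85 ± 0.07 and Il4 lower at -2.11 ± 0.51 among 5 genes (0.41). Interferon genes had 3 of 12 higher and 3 lower (0.67), and the cell cycle list had Stmn1 alone of 11 lower, at -0.36 ± 0.08 (0.98). As log2 ratios of CPM + 1, Plin2 rose by 0.46 in library 2 alone, Il4 fell by 0.76 in library 1 alone, and Stmn1 fell by 0.55 and 0.17 in libraries 1 and 2. Adjusted over the list alone the counts of these 8 lists were 2 higher, 4 higher with 1 lower, 9 lower, 5 higher with 2 lower, 7 higher with 5 lower, 1 higher with 1 lower, 3 higher with 4 lower, and 1 lower. Genes of other cell types were also measured. Cd74, which B and myeloid cells express, was higher by 2.22 ± 0.12, Cd79b by 3.02 ± 0.29 and Igkc by 2.26 ± 0.28, so that 1 of 6 myeloid genes (camera adjusted p = 0.013, and 0.47 with an estimated correlation) and 3 of 4 B cell genes (9.3e-06 and 0.29) were higher, with the same counts over the list alone. None of 6 adipose tissue genes was called by edgeR, over all genes or over the list alone, and 0 had an unadjusted p under 0.05 (0.91).

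Altogether edgeR called 2367 of 12940 genes, 1331 higher and 1036 lower in Foxp3-positive cells. Scaled by library size only, it called 2103 higher and 610 lower, and the median log2 fold change over all genes moved from -0.01 to 0.11. Foxp3-positive cells had more UMIs, 7941 against 6898 per cell in library 1 and 5465 against 4665 in library 2. With cells thinned to 1300 UMIs 619 genes were called, and DESeq2 called 738, without Gzma, Plin2, Il4 and Stmn1. Sums per hashed sample, with the hashed sample as block, gave 1460 calls among 7688 genes. The classes were 350 and 3381 cells in library 1 and 498 and 7809 in library 2, and cells with undetected Foxp3 remained in the second class.

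Among Foxp3-positive cells, those with Il1rl1 had more of most adipose Treg genes. Il1rl1 encodes ST2, the receptor for IL-33. Cells with an Il1rl1 UMI had more Areg, by 2.92 ± 0.17 log2 units with 226 CPM against 29.7, and more of the lipid regulator gene Pparg, by 2.93 ± 0.46 with 31.1 CPM against 3.99. Chemokine and leukotriene receptors rose with them, Ccr1 by 4.15 ± 0.50 and Ltb4r1 by 2.83 ± 0.17, as did Pcsk1 by 4.83 ± 0.50, Tox2 by 3.24 ± 0.38 and Cxcl2 by 2.88 ± 0.14. The chemokine gene Ccl4 fell by 4.80 ± 0.53, Dapl1 by 2.91 ± 0.30, Gpr18 by 2.52 ± 0.41 and the Treg surface gene Gpr83 by 1.91 ± 0.44. Of 20 adipose Treg genes 17 were higher and none lower (19 over the list alone). All 16 immediate early genes were higher (16 over the list alone), with Zfp36 at 1.76 ± 0.12 and Fos at 1.69 ± 0.09. Cell cycle genes were higher in 9 of 11 (11 over the list alone), and repair products in 8 of 10 (8). Naive genes were lower in 11 of 13 and higher in 1 (12 and 1 over the list alone), with Ccr7 at -1.42 ± 0.20. Treg core genes split, 8 of 18 higher and 4 lower, with Izumo1r at -1.36 ± 0.14. Camera gave adjusted p-values of 2.4e-27, 2.3e-29, 2.5e-12, 3.6e-14, 2.3e-12 and 0.035 for these lists, and 0.44, 0.44, 0.44, 0.44, 0.44 and 0.55 with an estimated correlation. Of 10 lipid genes 4 were higher (5 over the list alone), with Plin2 at 2.01 ± 0.20 (camera adjusted p = 7.0e-04, and 0.49 with an estimated correlation). Gata3 rose by 1.25 ± 0.13. The antigen presentation gene H2-Ab1, a marker of other cell types, rose by 2.72 ± 0.71, with log2 ratios of CPM + 1 of 1.62 in library 1 and 3.80 in library 2.

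In all, edgeR called 830 of 8772 genes between Il1rl1-positive and Il1rl1-zero cells, 497 higher and 333 lower. The classes were small, 93 and 62 cells with Il1rl1 against 257 and 436 without, and deeper, with 9393 against 7416 UMIs per cell in library 1 and 6396 against 5333 in library 2. After thinning to 1300 UMIs 2 genes were called, and DESeq2 called 179, without Pcsk1, Gpr18, Gpr83 and H2-Ab1. The classes also differed in tissue, with Il1rl1 in 22 of 48 Foxp3-positive cells of VAT replicate 1 and 4 of 48 of spleen replicate 2. Sums per hashed sample, with the hashed sample as block, gave 181 calls among 1673 genes. The split gene was Il1rl1, 1:40429570-40465415 in mm10 (ENSMUSG00000026069.15, protein coding).

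Foxp3-positive cells with Cxcr3 expressed a Th1 program and cell cycle genes. Cxcr3 encodes the receptor for interferon-induced chemokines. Cells with a Cxcr3 UMI had more Ccl5, by 2.31 ± 0.11 with 1140 CPM against 239, more Ifng by 2.01 ± 0.23 and more Nkg7 by 1.85 ± 0.15. Genes of DNA replication and mitosis rose too, Cdk1 by 3.13 ± 0.42, Rrm2 by 2.67 ± 0.37 and Stmn1 by 1.75 ± 0.20, most of it in library 2, where the log2 ratios of CPM + 1 were 3.45, 3.96 and 3.04 against 2.13, 1.07 and 0.73 in library 1. Cxcl2, which was high in Il1rl1-positive cells, fell by 1.74 ± 0.16, Penk by 1.63 ± 0.32 and Gpr83 by 1.74 ± 0.32. Of 11 Th1 genes 9 were higher (9 over the list alone), with Tbx21 at 1.72 ± 0.27, and of 11 cell cycle genes 9 were higher (11 over the list alone). Naive genes were lower in 9 of 13 (12 over the list alone). Of 21 adipose Treg genes 4 were higher, with Id2 at 1.03 ± 0.12, and 3 lower, with Areg at -0.83 ± 0.18 (-0.30 in library 2 alone), or 5 and 3 over the list alone. Camera gave adjusted p-values of 2.5e-39, 2.4e-30, 8.5e-21 and 0.95 for these lists, and 0.68 with an estimated correlation for the first 3. The count by edgeR was 345 of 8597 genes, 223 higher and 122 lower. Cells with Cxcr3 were deeper, at 9512 against 7122 UMIs in library 1 and 7236 against 4611 in library 2. DESeq2 called 24 genes, of which 21 were higher and which left out Ifng, Tbx21, Cxcl2, Penk, Gpr83, Areg and the cell cycle genes, and 1 gene was called after thinning. Sums per hashed sample, with the hashed sample as block, gave 41 calls among 1833 genes, without Id2. The classes also differed in tissue, with Cxcr3 in 30 of 47 Foxp3-positive cells of SAT replicate 1 and 3 of 48 of spleen replicate 2. Cells with hashtags of more than 1 sample were kept in the classes. Without them 405 of 7934 genes were called, with 97 and 118 cells with Cxcr3 against 213 and 287, Ccl5 rose by 2.63 ± 0.12 and Cdk1 by 3.42 ± 0.45, and Areg was not called. The classes were 120 and 162 cells with Cxcr3 against 230 and 336, and Cxcr3 lies at X:101731535-101734269 in mm10 (ENSMUSG00000050232.6, protein coding).

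Among T cells without Foxp3, Cxcr6 marked effector cells. Cxcr6 encodes the receptor for CXCL16 and is found on tissue T cells. Cells with a Cxcr6 UMI had more of the chemokine receptor gene Ccr2, by 2.83 ± 0.06, more Itga1, which encodes a collagen-binding integrin, by 2.86 ± 0.09, more Ltb4r1 by 3.43 ± 0.14, and more S100a4 by 2.53 ± 0.04. The lymph node homing gene Ccr7 fell by 2.21 ± 0.06, with Igfbp4 at -2.35 ± 0.06 and Gzma at -2.69 ± 0.12. All 12 Th1 genes were higher, with Ifng at 2.25 ± 0.08 and Il12rb2 at 2.34 ± 0.16, and all 13 naive genes lower. Genes of other helper types rose as well, the cytokine gene Il4 by 3.41 ± 0.23 and the Th17 markers Tmem176a by 2.43 ± 0.13 and Tmem176b by 2.31 ± 0.12. Of 20 adipose Treg genes 16 were higher, with Fgl2 at 2.87 ± 0.06. Treg cells with undetected Foxp3 can remain in both classes, and their part in this was not tested. Cell cycle genes were higher in 10 of 11, repair products in 8 of 9, with Lgals3 at 2.51 ± 0.09, and T cell receptor activation genes in 11 of 13, with Il2 at 2.34 ± 0.08. Adjusted over the list alone these counts were the same. Camera gave adjusted p-values of 1.3e-56 for Th1, 1.5e-68 for naive, 2.7e-28 for adipose Treg, 1.8e-27 for cell cycle, 4.5e-22 for repair and 3.0e-18 for activation genes, and with an estimated correlation these were 0.35, 0.35, 0.38, 0.35, 0.35 and 0.35. Ighm, a B cell gene, was lower by 0.70 ± 0.05 and the adipocyte and endothelial gene Fabp4 higher by 0.59 ± 0.13, the latter in edgeR and not in DESeq2. Across all genes edgeR called 5703 of 12861, 3004 higher and 2699 lower. Scaling by library size only gave 4617 higher and 1494 lower and moved the median of all genes from -0.01 to 0.16. The classes were 928 and 1572 cells with Cxcr6 against 2453 and 6237, at 7861 against 6534 UMIs per cell in library 1 and 5450 against 4468 in library 2. After thinning 1781 genes were called, and DESeq2 called 2559. The classes also differed in tissue, with 205 and 196 cells of SAT replicate 1 against 17 and 284 of spleen replicate 1, and with sums per hashed sample and the hashed sample as block 2945 of 8025 genes were called. Cxcr6 lies at 9:123806475-123811760 in mm10 (ENSMUSG00000048521.8, protein coding).

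The genes that defined these classes were found in other cell types as well. Foxp3 had a UMI in 9.38% (350 of 3731) and 5.99% (498 of 8307) of T cells of libraries 1 and 2. Fibroblasts and B cells of the same libraries, which should lack it, had it in 3.43% (6 of 175) and 1.37%. Their median depths were 5351 and 2826 UMIs against 6110 and 4451 in T cells. Naive-like T cells, at 6060 and 4977 UMIs, had it in 1.93% and 0.409%. For Cxcr6 the shares were 26.7% and 19.8% in T cells, 6.29% and 6.85% in the other cell types, and 1.61% and 1.06% in naive-like cells. Cxcr3 was found in 33.9% and 27.3% of T cells, in 5.14% and 19.2% of the other types, and in 2.49% and 1.60% of naive-like cells. Il1rl1 was found in 4.61% and 2.02% of T cells against 1.71% and 2.74% of the other types, so in library 2 its share over all T cells was not above theirs, while naive-like cells had 0.241% and 0.0818%. The 95% intervals of T cells and of the other types overlapped for Foxp3 and Cxcr3 in library 2 and for Il1rl1 in both libraries. With cells of at least 1300 UMIs thinned to that depth the T cell shares were 3.94% and 2.74% for Foxp3, 2.2% and 0.83% for Il1rl1, 12.9% and 13.2% for Cxcr3 and 11.4% and 10.3% for Cxcr6.

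Foxp3-positive cells of SAT and VAT carried more transcripts of effector, repair and stress genes than those of spleen. In VAT the ST2 gene Il1rl1 was higher than in spleen by 3.19 ± 0.36 log2 units, Areg by 3.81 ± 0.52, Il10 by 4.11 ± 0.89 and Cxcl2 by 3.76 ± 0.50 (± SE, n = 4 hashed samples per tissue). SAT had more Areg as well, by 2.49 ± 0.60, and the genes of cytotoxic and Th1 cells stood out, Nkg7 by 4.49 ± 0.45, Ccl5 by 3.94 ± 0.51, Gzmb by 3.76 ± 0.80 and Ifng by 3.56 ± 0.62. Ccr3, an eotaxin receptor gene, rose in both, by 4.49 ± 0.78 in SAT and 4.58 ± 0.77 in VAT, and so did Cxcr6, by 3.15 ± 0.41 and 3.68 ± 0.38. The immediate early gene Fosb rose by 4.71 ± 0.37 and 5.16 ± 0.35 and Dusp1 by 3.99 ± 0.30 and 4.34 ± 0.30. Spleen cells had more Gpr83, with -2.17 ± 0.45 for SAT and -2.30 ± 0.45 for VAT.

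Lists moved with these genes in both depots. Against spleen, adipose Treg genes were higher in 13 of 18 in SAT and 16 of 18 in VAT (16 and 17 over the list alone), with Klrg1 at 2.31 ± 0.25 in SAT and Ccr2 at 2.61 ± 0.26 in VAT. Their camera adjusted p was 1.8e-16 and 1.8e-26, and with an estimated correlation the adjusted p was 0.0037 and 0.0011. Th1 genes were higher in 8 of 11 in each (9 and 8 over the list alone), with adjusted p = 0.0030 and 0.0086 with an estimated correlation. Repair products were higher in 6 and 7 of 9 (8 and 7 over the list alone; 0.0013 and 0.0011), and immediate early genes in 13 and 15 of 15 (15 in each over the list alone; 8.0e-04 and 3.1e-04), with Cd69, an activation gene of another list, at 2.31 ± 0.24 and 2.76 ± 0.23. Naive genes were lower in 8 of 13 in each (12 and 11 over the list alone; 0.039 and 0.044), with 1 higher in VAT. Treg core genes split, 8 of 16 higher and 3 lower in SAT and 6 higher and 2 lower in VAT (9 and 4, and 6 and 2, over the list alone), with Ctla4 at 1.43 ± 0.21 in SAT and Izumo1r at -1.37 ± 0.17 and -1.39 ± 0.17 in SAT and VAT. Their camera adjusted p was 0.013 and 0.014, and with an estimated correlation 0.23 and 0.22. Interferon genes were lower in 3 of 8 in VAT (4 over the list alone), with a camera adjusted p of 0.0022 that became 0.087 with an estimated correlation. Lipid genes in VAT were higher in 3 of 6, Dgat1 at 2.37 ± 0.43 and Plin2 at 2.28 ± 0.43 (0.0019 and 0.10). Cd74, which B and myeloid cells express at a high level, was higher by 1.81 ± 0.35 in SAT and 1.23 ± 0.37 in VAT. Of 5281 genes edgeR called 557 for SAT against spleen, 318 higher and 239 lower, and 626 for VAT against spleen, 355 higher and 271 lower. Scaling by library size only gave 403 higher and 183 lower for SAT. Sums of thinned cells gave 199 and 231 calls, and DESeq2 gave 367 for SAT.

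Foxp3-positive cells of BAT had more of the naive cell genes than those of SAT and VAT, and less of the adipose Treg genes than those of VAT. Satb1, which encodes a chromatin organizer, was higher in BAT than in SAT by 1.70 ± 0.37, with 373 CPM against 121, and higher than in VAT by 2.63 ± 0.39 (± SE, n = 2 hashed samples of BAT and 4 of each other tissue). Actn1 was higher by 1.89 ± 0.50 and 2.62 ± 0.54. The inflammatory chemokine receptor gene Ccr2 was lower by 2.56 ± 0.47 against SAT, with 48.0 CPM against 254, and by 3.01 ± 0.45 against VAT, and Cxcr6 by 2.44 ± 0.62 and 2.97 ± 0.58. The galectin gene Lgals3 was lower by 3.02 ± 0.58 and 3.37 ± 0.56. Against VAT alone Areg was lower by 5.38 ± 1.12, with 5.59 CPM against 202, Il1rl1 by 1.70 ± 0.47 and Il2ra by 1.93 ± 0.49. The BAT level of Areg lay near the floor of detection, as each BAT sum held 28 cells, so the size of that change is uncertain. Against SAT alone Anxa1 was lower by 2.68 ± 0.64 and Klrg1 by 1.56 ± 0.36. Against spleen the Foxp3-positive cells of BAT had more stress and early genes, with Hspa1b at 4.34 ± 0.51, Jun at 3.64 ± 0.48 and Cd69 at 2.51 ± 0.31, and more Ccl5, at 3.33 ± 0.66.

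Naive genes were higher in BAT in 7 of 13 against each depot (10 against SAT and 8 against VAT over the list alone), with camera adjusted p of 4.4e-16 and 9.0e-17, and adjusted p = 0.019 and 0.014 with an estimated correlation. Repair products were lower in 2 of 9 against SAT and 4 of 9 against VAT (5 and 6 over the list alone; 0.019 and 0.0068 with an estimated correlation). Adipose Treg genes were lower in 3 of 18 with 1 higher against SAT (5 and 1 over the list alone), with a camera adjusted p of 5.0e-06 that became 0.12 with an estimated correlation, and lower in 5 of 18 against VAT (11 over the list alone), where the adjusted p was 0.015 with an estimated correlation. Th1 genes were lower in 2 of 11 against SAT (7 over the list alone; 1.2e-05 by camera and 0.08 with an estimated correlation). Against spleen, 8 of 15 immediate early genes were higher (10 over the list alone; adjusted p = 1.7e-04 with an estimated correlation) and 1 of 11 activation genes (5 higher and 1 lower over the list alone; 0.0075). Of 5281 genes edgeR called 132 for BAT against SAT, 83 higher and 49 lower, 156 for BAT against VAT, 81 and 75, and 19 for BAT against spleen, 18 and 1. Of the 19 genes called against spleen 18 had the same direction in both experiments. With scaling by library size only, the genes called higher and lower were 51 and 72 against SAT and 56 and 86 against VAT. The median of all genes moved from -0.01 to -0.13 and to -0.11. BAT rested on replicates 1 and 4, of 28 cells each. Replicate 4 had a weak hashtag, with a separation of 2.64 robust standard deviations, so some of its cells may belong to other samples. The stricter hashtag margin kept 448 of the 747 cells given to that replicate. Without BAT replicate 1 the count against SAT was 1, against VAT 14 and against spleen 12, and without BAT replicate 4 they were 26 and 60. With BAT replicates of at least 10 cells, which brought in the other two, the counts were 234 and 270. With Treg-like clusters in place of Foxp3, where BAT had replicates 3 and 4, the counts against SAT and VAT were 37 and 47. Satb1 and Cxcr6 were called there against both and Klrg1 against SAT, and the other genes named above for SAT and VAT were not. In Foxp3-positive cells of those clusters, where BAT had 22 cells of replicate 4, the counts were 6 and 16, with none of the named genes. The Foxp3 share of BAT replicates 1 and 2, 5.82% and 3.66%, compares with 3.43% in the other cell types and 1.93% in naive-like cells of library 1. DESeq2 did not call Actn1, Anxa1 and Cxcr6 against SAT, Il1rl1 against VAT or Ccl5 against spleen, and with the stricter hashtag margin Actn1 and Klrg1 against SAT were not called. On simulated counts at these depths 71.2%, 68.2% and 65.2% of genes with 4-fold changes were recovered in the 3 BAT comparisons. Of genes with 2-fold changes 13.4%, 19.4% and 16.4% were recovered.

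Foxp3-positive cells of SAT and VAT differed in few genes, in a number that another split of the same samples exceeded. The IL-33 receptor gene Il1rl1 was lower in SAT by 1.51 ± 0.28, with 66.2 CPM against 192, and Cxcl2 by 3.90 ± 0.52, with 33.5 CPM against 557 (n = 4 hashed samples each). The cold-inducible RNA-binding protein genes Cirbp and Rbm3 were lower in SAT by 1.40 ± 0.23 and 0.74 ± 0.14, and the early response genes Zfp36 by 0.94 ± 0.17 and Klf6 by 0.73 ± 0.17. SAT had more of the interferon-induced GTPase gene Igtp, by 1.04 ± 0.23, and of Cacybp, by 0.85 ± 0.16. The chaperone genes Hspe1 and Hspa8 were higher by 0.98 ± 0.21 and 0.47 ± 0.11, while the heat shock gene Hspa1b was lower by 1.55 ± 0.26. Of 8 interferon genes 1 was higher (6 over the list alone), with a camera adjusted p of 5.7e-09 and 0.014 with an estimated correlation. Of 15 immediate early genes 4 were lower (7 over the list alone; 1.7e-18 and 0.014). Of 18 adipose Treg genes 2 were lower (5 over the list alone), with a camera adjusted p of 2.3e-08 that became 0.089 with an estimated correlation. The 16 Treg core genes had a median log2 fold change of -0.06 (0.78). In total edgeR called 18 of 5281 genes, 7 higher and 11 lower in SAT. Without the experiment as a term 3 were called and with the stricter hashtag margin 5. Cirbp was called in both, while Il1rl1, Rbm3, Zfp36, Cacybp, Hspe1 and Hspa8 were called in neither, and DESeq2 did not call Cxcl2, Igtp and Hspe1. With single samples left out the count lay between 7, without SAT replicate 1, and 51, without SAT replicate 4. Without SAT replicate 2 or VAT replicate 1 it was 9. Of 35 splits of these 8 samples 1 other gave at least as many genes, 25, so chance cannot be excluded for the count.

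Foxp3-zero cells of SAT and VAT expressed the genes of effector cells above their level in spleen. In SAT the Th1 cytokine gene Ifng was higher than in spleen by 5.12 ± 0.26, Ccl5 by 4.16 ± 0.15, with 2330 CPM against 130, Fgl2 by 5.22 ± 0.23 and Ly6c2 by 4.52 ± 0.20 (n = 4 hashed samples each). In VAT Ifng was higher by 4.43 ± 0.27, the galectin gene Lgals3 by 4.72 ± 0.40, Il1rl1 by 4.55 ± 0.42 and the Th17 marker Tmem176b by 3.39 ± 0.22. Fosb rose in both, by 5.33 ± 0.27 and 5.03 ± 0.28. Dapl1 fell by 1.89 ± 0.20 in SAT and 1.55 ± 0.19 in VAT. All 13 Th1 genes and all 15 immediate early genes were higher in each depot, and all 7 repair products (the same over the list alone). With an estimated correlation their adjusted p was 0.0037, 0.0048 and 0.0048 in SAT and 0.0029, 0.0029 and 0.0059 in VAT. Of 17 adipose Treg genes 16 were higher in SAT, with 1 lower, and 15 in VAT (the same over the list alone; 0.0056 and 0.0047). Naive genes were lower in 13 of 13 in SAT and 11 of 13 in VAT (the same over the list alone), with camera adjusted p of 5.5e-12 and 8.3e-10 that became 0.072 and 0.10 with an estimated correlation. Treg core genes were higher in 10 of 16 in VAT with 1 lower (11 and 1 over the list alone; 0.025), and in SAT in 10 with 2 lower (10 and 3 over the list alone), with a camera adjusted p of 1.6e-04 that became 0.072 with an estimated correlation. Treg cells with undetected Foxp3 can remain among Foxp3-zero cells, here and in the comparisons below. Whether they gave the differences in Il1rl1, Treg core and adipose Treg genes was not tested. Fabp4, an adipocyte and endothelial gene, was higher by 0.86 ± 0.24 in SAT and 1.02 ± 0.23 in VAT, and the B cell gene Ighm lower by 0.61 ± 0.10 and 0.50 ± 0.10. The Fabp4 calls were lost without the experiment as a term. The counts were 4155 of 10306 genes for SAT, 2201 higher and 1954 lower, and 3793 for VAT, 2051 and 1742. Scaled by library size only they were 2937 and 1277 for SAT, where the median of all genes moved from -0.01 to 0.10, and 2484 and 1271 for VAT. Sums of thinned cells gave 1624 and 1453.

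The Foxp3-zero cells of BAT differed from those of spleen in fewer genes than from those of SAT and VAT, except within naive-like cells, where 675 of 7303 genes were called against spleen, 74 against SAT and 349 against VAT. Against SAT the Th1-related genes Ly6c2 and Ifng were lower in BAT by 3.26 ± 0.18 and 2.71 ± 0.20, and Gzmb and Klrg1 by 3.05 ± 0.29 and 3.05 ± 0.26. Against VAT Il1rl1 was lower by 3.90 ± 0.41, Tmem176b by 3.25 ± 0.23 and Ly6c2 by 2.87 ± 0.18. The naive cell genes Dapl1 and Satb1 were higher by 1.85 ± 0.20 and 1.60 ± 0.14 against SAT and by 1.52 ± 0.20 and 1.42 ± 0.14 against VAT. Within naive-like cells this was not seen, with 7 of 13 naive genes lower in BAT than in SAT (adjusted p = 0.047 with an estimated correlation) and 5 of 13 lower than in VAT (0.42). The cluster led by Hspa1b holds 35.4 of the 55.7 points of naive-like cells in BAT and 4.89 of 17.5 in SAT, and without it 3 of 13 were lower than in SAT (0.19) and 1 was higher and 1 lower than in VAT (0.93). Against spleen BAT had more Hspa1a, by 4.94 ± 0.35, Jun by 4.06 ± 0.20, Ifng by 2.41 ± 0.35, Nkg7 by 2.04 ± 0.20 and Ccl5 by 1.85 ± 0.15, and less of the interferon-induced genes Isg15, by 1.24 ± 0.29, and Ifit1, by 1.21 ± 0.30. All 13 Th1 genes were lower than in SAT and in VAT (the same over the list alone; adjusted p = 0.0038 and 0.0042 with an estimated correlation), and 8 of 13 were higher than in spleen (9 over the list alone; 0.026). Immediate early genes were higher than in spleen in 12 of 15 (14 over the list alone; 5.0e-04). All 12 interferon genes were lower than in SAT (12 over the list alone), with a camera adjusted p of 1.7e-08 that became 0.082 with an estimated correlation, and 4 of 12 were lower than in spleen (6; 5.2e-10 and 0.079). Of 13 naive genes 1 was called against spleen, lower (1 higher and 1 lower over the list alone; 0.79 by camera). The counts were 3696 of 10306 against SAT, 1749 higher and 1947 lower, 3314 against VAT, 1547 and 1767, and 883 against spleen, 571 and 312. Scaling by library size only gave 980 and 3005, 985 and 2523, and 465 and 435, and moved the median of all genes from 0.01 to -0.14 against SAT and from 0.00 to -0.11 against VAT. Without the experiment as a term the counts were 2438, 1961 and 323, and sums of thinned cells gave 1471, 1280 and 232.

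Foxp3-zero cells of SAT had more of the interferon genes, and those of VAT more of the Th17 genes. The cytotoxic and chemokine genes Gzmb and Xcl1 were higher in SAT by 2.15 ± 0.25 and 2.05 ± 0.22, and the interferon-induced genes Isg15 and Ifit1 by 1.57 ± 0.23 and 1.54 ± 0.26 (n = 4 hashed samples each). Ltb4r1, Il1rl1, Tmem176a and Tmem176b were lower in SAT by 2.22 ± 0.31, 1.89 ± 0.29, 1.85 ± 0.20 and 1.75 ± 0.18. The cold-inducible genes Cirbp, at 10:80165985-80172786 (ENSMUSG00000045193.13), and Rbm3, at X:8138975-8145880 (ENSMUSG00000031167.16), both protein coding in mm10, were lower in SAT by 0.98 ± 0.09 and 0.88 ± 0.08. All 12 interferon genes were higher in SAT (12 over the list alone), with a camera adjusted p of 1.1e-21 and 0.020 with an estimated correlation. Interferon-response-like clusters held 6.41% ± 3.85 of CD4 T cells in SAT and 2.28% ± 1.40 in VAT (mean ± SD). Without SAT replicate 4 the share of SAT was 4.61%. Whether these clusters carried the list difference was not tested. Of 3 Th17 genes 2 were lower (2 over the list alone; 3.5e-14 and 0.0029). Th1 genes were higher in 4 of 13 (8 higher and 1 lower over the list alone), with a camera adjusted p of 2.9e-04 that became 0.45 with an estimated correlation. Of 7 repair products 3 were higher (4 over the list alone; 3.2e-06 and 0.064), and Cd74 was higher by 1.07 ± 0.28, a call that the stricter hashtag margin ended. For this comparison edgeR called 443 of 10306 genes, 255 higher and 188 lower in SAT, and 380 and 145 with scaling by library size only. DESeq2 called 282, and 72 were called without the experiment as a term, 291 with the stricter hashtag margin and 191 from thinned cells. With single samples left out the count was 224 without SAT replicate 1, 222 without SAT replicate 4, 255 and 253 without VAT replicates 3 and 4, and 665 without SAT replicate 3.

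**Figure D3:**
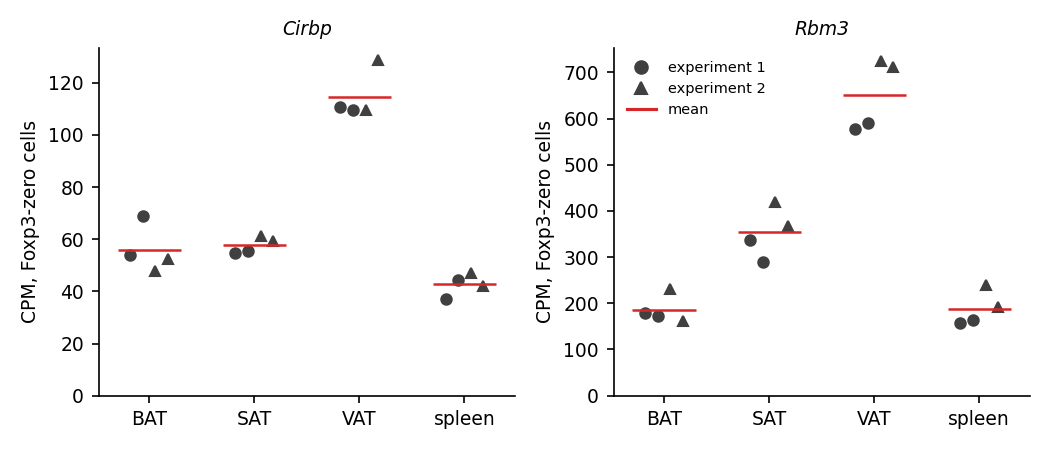
CPM of Cirbp and Rbm3 (y axes) in the Foxp3-zero cells of each hashed sample by tissue (x axis); shapes give the experiment and lines are means of 4. Cirbp lay at 109 to 129 CPM in VAT and at 37.1 to 68.9 in the other tissues.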

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

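The tests of whether a tissue difference depends on Foxp3 were chosen after the tissue comparisons had been seen, and the outlying values were read for the shares, depths and CPM printed in the report.

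Some tissue differences were not the same in Foxp3-positive and Foxp3-zero cells, by a test of the difference of differences in edgeR over 10154 genes. The number of such genes was 111 for SAT against spleen, 94 for VAT against spleen, 13 for SAT against VAT, 9 for BAT against SAT, 6 for BAT against VAT and 3 for BAT against spleen. Of the 111 genes 94 had the more negative difference in Foxp3-positive cells. Th1-effector-like cells made up 36.1% of CD4 T cells in SAT and 1.44% in spleen, so Foxp3-zero cells also changed in their mix of classes. Whether that mix gave these differences was not tested, so they do not show a weaker response of Treg cells. The genes named in this paragraph were chosen after their values were seen. The integrin gene Itgb1 was raised in SAT over spleen by 2.84 ± 0.17 log2 units less in Foxp3-positive than in Foxp3-zero cells, S100a4 by 2.61 ± 0.25 less and S100a6 by 2.03 ± 0.19 less. In the other direction the early response gene Zfp36 rose by 1.24 ± 0.24 more in Foxp3-positive cells. For BAT against spleen the 3 genes were the costimulatory receptor gene Tnfrsf4, at 1.93 ± 0.33, Ikzf2 at 1.22 ± 0.24 and Tent5a at 2.09 ± 0.41, all with the more positive difference in Foxp3-positive cells.

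These counts depended on the setting. For SAT against spleen the count was 86 with DESeq2, 129 with scaling by library size only, 159 with no filter, 91 with the stricter hashtag margin and 27 from thinned cells. With single samples left out it lay between 69, without spleen replicate 3, and 168, without SAT replicate 3. For VAT against spleen the values were 62, 89, 137, 108 and 24, and 69 to 100 with single samples left out. Of 35 splits of the 8 samples, only the real one gave as many as 111 genes for SAT against spleen, the highest other split giving 51. Only the real one gave 94 for VAT against spleen, the highest other giving 5. The other splits mix the tissues, so a tissue difference can lower their counts. Of the 35 splits 18 keep as many samples of each experiment on both sides, too few for a share under 0.05. Within experiments chance was therefore not excluded for either count. For SAT against VAT 2 of 35 splits gave at least 13 genes, the highest other 15, and the split that follows the experiments gave 12, so chance cannot be excluded there. That count went to 2 with DESeq2 and to 36 without SAT replicate 4, and to 7, 8 and 6 without SAT replicate 1, SAT replicate 2 and VAT replicate 2. The 3 counts that involve BAT rest on 2 samples of Foxp3-positive cells, and DESeq2 gave 24, 19 and 3 for BAT against SAT, VAT and spleen. Without BAT replicate 1 the edgeR counts were 3, 5 and 1. The count for BAT against SAT was 22 without SAT replicate 3 and 21 without SAT replicate 4, that for BAT against VAT was 10 without VAT replicate 1 and 4 without VAT replicate 2, and that for BAT against spleen was 6 without spleen replicate 1 and 1 without spleen replicate 3.

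Outlying samples were looked for in 58 groups of 4, and 2 were found, where chance gives about 1 in 20 groups. The NKT-like share of BAT replicate 3 was 2.45%, against 1.22% to 1.31% in the other BAT samples. In Foxp3-zero cells of VAT the Cirbp level of replicate 4 was 129 CPM, against 109 to 111 in the others. Neither was left out of a test.

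Hashtags that the labels do not tie to a sample had 4843 counts in library 1 and 6941 in library 2, above the limit that a count of 0 allows. They made up 0.0856% and 0.0964% of hashtag counts.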

How the results depend on the processing

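The alternatives named in processing as added, with the estimated correlation in tissue comparisons and sums of thinned cells there, were chosen after the results had been seen. The other settings were planned. Why a setting moved a count was not tested.

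The counts of genes in the class comparisons moved most with DESeq2, with thinned cells, which also changed the classes, with no block and with sums per hashed sample. With DESeq2 the counts were 738 for Foxp3, 179 for Il1rl1, 24 for Cxcr3 and 2559 for Cxcr6, against 2367, 830, 345 and 5703 in edgeR. With cells thinned to 1300 UMIs before they were split they were 619, 2, 1 and 1781. Without the library as replicate block they were 574, 293, 12 and 1694. With sums per hashed sample and the hashed sample as replicate block they were 1460, 181, 41 and 2945. The Il1rl1 count was 388 with at least 2 UMIs of the gene, 543 with Treg-like clusters as the population, 467 without hashtag multiplets and 553 without the low-UMI cluster. The count of the Foxp3 comparison stayed within 1.5 times of 2367 with Treg-like clusters in place of Foxp3, without naive-like cells, with at least 2 UMIs, with no filter or a stricter one, and without multiplets or the low-UMI cluster. Library-size scaling left all 16 counts of genes within 1.5 times, and changed how they divided between higher and lower as given in the report.

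In the tissue comparisons of Foxp3-positive cells, no experiment term gave 44 genes for BAT against SAT, 64 for BAT against VAT and 3 for SAT against VAT. No filter gave 63 for SAT against VAT and 47 for BAT against spleen, and DESeq2 gave 367 for SAT against spleen. Sums of thinned cells gave 77 for BAT against SAT, 82 for BAT against VAT, 7 for SAT against VAT, 11 for BAT against spleen, 199 for SAT against spleen and 231 for VAT against spleen. The stricter hashtag margin gave 64 for BAT against SAT and 5 for SAT against VAT. Samples of at least 10 cells gave 234, 270 and 37 for BAT against SAT, VAT and spleen, Treg-like clusters in place of Foxp3 gave 37, 47 and 40, and Foxp3-positive cells of Treg-like clusters gave 6 and 16 against SAT and VAT. With single samples left out, BAT against SAT ran from 1 to 149, with 1 without BAT replicate 1 and 26 without BAT replicate 4. BAT against VAT ran from 14 to 170, with 14 without BAT replicate 1 and 60 without BAT replicate 4. BAT against spleen ran from 12, without BAT replicate 1, to 20. SAT against VAT ran from 7 to 51, with 7 without SAT replicate 1, 9 without SAT replicate 2 or VAT replicate 1, and 51 without SAT replicate 4. Where 1 BAT sample was left, it was assumed to vary like the other samples. These BAT counts therefore rest on single samples of 28 cells.

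In Foxp3-zero cells, no experiment term gave 2438 for BAT against SAT, 1961 for BAT against VAT, 72 for SAT against VAT and 323 for BAT against spleen. Sums of thinned cells gave 1471, 1280, 191 and 232 for these, 1624 for SAT against spleen and 1453 for VAT against spleen. For SAT against VAT DESeq2 gave 282, no filter 698 and the stricter margin 291. With single samples left out it ran from 222 to 665, with 224 without SAT replicate 1, 665 without SAT replicate 3, 222 without SAT replicate 4, 255 without VAT replicate 3 and 253 without VAT replicate 4. A replicate block by number in place of the experiment left all 12 tissue counts within 1.5 times.

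Genes were also counted in other splits of the same samples. These splits mix the tissues, so a tissue difference adds to the spread within their groups and can lower their counts. They do not tell how many genes would be called without a tissue difference. In Foxp3-positive cells only the real split of 35 gave 557 genes for SAT against spleen, the highest other giving 7, and only the real one gave 626 for VAT against spleen, the highest other giving 1. For SAT against VAT 2 splits gave at least 18, the highest other 25 by an exchange of SAT replicate 4 and VAT replicate 3, so chance cannot be excluded for that count. In Foxp3-zero cells 1 split of 35, the real one, gave the full count in each of the 6 comparisons. The real and highest other counts were 3696 and 1 for BAT against SAT and 3314 and 0 for BAT against VAT. For SAT against VAT they were 443 and 68, and for BAT against spleen 883 and 3. They were 4155 and 1 for SAT against spleen and 3793 and 0 for VAT against spleen. Of the 35 splits 18 keep as many samples of each experiment on both sides, too few for a share under 0.05. Chance was therefore not excluded within experiments. The SAT against VAT count was 72 without the experiment term.

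For the genes that the naming rule gave and the list members followed, 6172 of 6882 values kept their call and direction, 708 lost the call, and 2 were reversed. Xcl1 in Cxcr3-positive cells became -0.37 with Treg-like clusters as the population, and Sdad1 in BAT against SAT became -0.43 in Foxp3-positive cells of Treg-like clusters. By setting, DESeq2 kept 379 of 475 calls, library-size scaling 465 of 475, no filter 473 of 475, no experiment term 272 of 326 and single samples left out 2191 of 2457. Genes that the filter of a setting removed were not counted, neither as kept nor as lost. Of 149 values in the class comparisons, cells thinned before they were split left 91, of which 73 were kept. Sums per hashed sample left 67, of which 65 were kept. In class comparisons with 1 library alone, which gives a value with no test, 180 of 298 values lay within the interval that the standard error of both libraries gives. The rule for naming genes asked for the same sign in both.

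Of the gene lists, 14 passed camera for Foxp3, 14 for Il1rl1, 6 for Cxcr3 and 14 for Cxcr6, and 0 with an estimated correlation or with fry in each. That correlation rests on 1 residual degree of freedom, and with it 1 list for Foxp3 and 0 for the other 3 had an unadjusted p under 0.05. Sums of thinned cells left 4 for Il1rl1 and 2 for Cxcr3, and 12 for Foxp3 and for Cxcr6. In Foxp3-positive cells the estimated correlation left 3 of 10 for BAT against SAT, 5 of 11 for BAT against VAT, 2 of 8 for SAT against VAT, 2 of 5 for BAT against spleen, 7 of 12 for SAT against spleen and 7 of 11 for VAT against spleen. In Foxp3-zero cells, in the same order, it left 7 of 12, 7 of 14, 2 of 8, 4 of 10, 6 of 11 and 8 of 12.

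Differences in the share of Foxp3-positive cells kept their sign for BAT against each other tissue in all settings, and 8 of 72 values changed sign, all among SAT, VAT and spleen. The stricter hashtag margin turned SAT minus VAT to 0.984 points and SAT minus spleen to 2.13, and thinned cells turned SAT minus spleen to 0.388. With single samples left out SAT minus spleen ran from -1.19 to 0.835, positive without SAT replicate 3, SAT replicate 4 or spleen replicate 2, and VAT minus spleen ran from -0.00159, without VAT replicate 2, to 2.13. Treg-like clusters in place of Foxp3 turned VAT minus spleen to -0.631.

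Shares of the splitting genes fell when cells were thinned, to 3.94% and 2.74% for Foxp3, 2.2% and 0.83% for Il1rl1, 12.9% and 13.2% for Cxcr3 and 11.4% and 10.3% for Cxcr6 in libraries 1 and 2. With the looser cell filter they were 5.36%, 1.73%, 24.6% and 17.95% in library 2.

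Class shares depended on the clustering. At resolution 0.5 libraries 1 and 2 had 46.9% and 43.8% naive-like, 26.6% and 17.2% Th1-effector-like and 6.40% and 4.80% NKT-like cells, and 0% Tfh-like and Th17-like cells. At resolution 1.5 they had 29.3% and 25.2% naive-like cells, and library 2 had 1.45% Th17-like cells. The looser filter gave 41.1% and 29.8% naive-like, 19.6% and 8.22% Th1-effector-like and 0% Tfh-like cells, with 5.36% NKT-like and 10.2% Treg-like cells in library 1 and 1.67% Th17-like cells in library 2. Components centred per library gave 46.1% and 36.8% naive-like, 20.6% and 11.7% Th1-effector-like and 6.30% and 5.61% NKT-like cells, and 5.61% Tfh-like cells in library 2. Without hashtag multiplets library 2 had 30.7% naive-like, 14.02% Th1-effector-like and 7.44% Treg-like cells. Per tissue 35 of 120 shares under another clustering, filter or hashtag margin moved by over 1 SD, 17 of them at resolution 0.5, while with 1 of 4 samples left out a mean cannot move so far. At that resolution Th1-effector-like cells of BAT and spleen made up 8.02% and 5.26%, naive-like cells of BAT, SAT, VAT and spleen 80.4%, 23.3%, 28.3% and 78.0%, NKT-like cells of SAT, VAT and spleen 15.8%, 6.99% and 0.146%, and Tfh-like and Th17-like cells 0% in all 4 tissues. The looser filter gave 69.1% and 66.7% naive-like cells in BAT and spleen, 0.896% and 0.579% Th17-like cells in these, 4.52% and 13.6% Treg-like cells in BAT and VAT, 6.70% NKT-like cells in VAT and 0% Tfh-like cells. Centred components gave 76.6% and 70.1% naive-like cells in BAT and spleen and 2.32%, 16.1% and 7.21% NKT-like cells in BAT, SAT and VAT. Resolution 1.5 gave 1.46% Th17-like cells in SAT, and the stricter hashtag margin 13.96% NKT-like cells there.

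Keeping the cells that Scrublet called doublets was planned and not run, since it called 0.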

Other observations

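Of the tests in this part, the one that drew SAT and VAT down to the cells of BAT was written before its result was seen, and the others were chosen after the results were seen.

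T cells of every fat depot had less of the microRNA host transcript Mir142hg than those of spleen, in both populations. In Foxp3-zero cells its log2 difference from spleen was -2.70 ± 0.15 in BAT, -3.09 ± 0.15 in SAT and -3.21 ± 0.15 in VAT, and in Foxp3-positive cells -3.01 ± 0.65, -3.17 ± 0.38 and -2.92 ± 0.37. Chchd10, which encodes a mitochondrial protein, was low in Foxp3-positive cells of VAT alone, 2.62 ± 0.45 below spleen, 2.18 ± 0.47 below SAT and 2.73 ± 0.64 below BAT. DESeq2 gave no adjusted p for the last 2 differences of Chchd10, nor for Mir142hg in Foxp3-positive cells of BAT. The chemokine gene Cxcl10 was higher in Foxp3-positive cells of VAT than of spleen by 4.70 ± 0.93.

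Foxp3-zero cells of BAT had less of the cholesterol synthesis genes Idi1 and Cyp51 than those of spleen, by 1.27 ± 0.22 and 1.18 ± 0.21, and of Sqle, by 1.18 ± 0.24. The lipid metabolism list as a whole had 1 of 11 genes higher and 3 lower there, and camera gave an adjusted p of 0.59. In SAT against VAT the receptor gene Tnfrsf4 and the matrix gene Ecm1 were lower in Foxp3-zero cells of SAT, by 0.87 ± 0.16 and 2.18 ± 0.21, and the NK receptor gene Cd160 was higher by 1.38 ± 0.18.

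Taken over all classes, CD4 T cells of BAT differed from spleen in fewer genes than those of SAT and VAT did, 19 against 557 and 626 in Foxp3-positive cells and 883 against 4155 and 3793 in Foxp3-zero cells. The small number of BAT samples and cells did not account for it, since SAT and VAT drawn down to the same samples and cells gave medians of 353.5 and 329 genes, and all 20 draws of each lay above 19. Naive-like Foxp3-zero cells of BAT and spleen differed in 9.24% of 7303 genes, so not all of those BAT cells were spleen cells that carried BAT hashtags. Whether a part of them were cannot be told from this, since a mixture would also leave genes that differ. Many naive-like cells of BAT lay in a cluster led by Hspa1b, which held 54.5% of BAT cells in experiment 1 and 16.4% in experiment 2. Without that cluster the naive-like cells of BAT and spleen differed in 7.60% of 6564 genes. The remaining naive-like clusters differed in share as well, with 7.02% and 13.2% of BAT cells against 27.4% and 11.4% of spleen cells. A different mix of classes could account for it in Foxp3-zero cells, but counts within naive-like cells cannot decide this. Only fat was digested, which can raise each count of a depot against spleen. The numbers of naive-like cells were also not matched, and their share was 55.7% in BAT and 17.5% in SAT. Within naive-like cells the count against spleen was 675 for BAT, 444 for SAT and 556 for VAT, and BAT differed from SAT in 74 genes and from VAT in 349. The latter is 62.8% of the count of VAT against spleen, into which the same VAT cells enter, and for SAT the percentage was lower. Without the cluster led by Hspa1b BAT differed from SAT in 17 genes and from VAT in 211, and SAT and VAT from spleen in 393 and 520. Cells of the blood left in BAT stay open, since no blood sample was in the design. A biological difference between depots stays open as well and was not tested.

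Immediate early and heat shock genes were higher in all 3 fat depots than in spleen, in both populations. A different mix of cell classes did not account for the rise in Foxp3-zero cells. Within naive-like Foxp3-zero cells the median log2 fold change of the list was 1.83 in BAT, 2.45 in SAT and 1.98 in VAT, with 12 of 14 genes called in each. The mix of classes was not tested in Foxp3-positive cells. Naive-like cells include a cluster led by Hspa1b, a gene of the list, and without it the medians were 1.56, 2.22 and 2.27. The digestion of fat and the fat itself cannot be told apart, because only fat was digested, and the lowest median over all Foxp3-zero cells was 1.69, in BAT. The same digestion could also have contributed to the other differences between fat and spleen.

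The cold-inducible genes Cirbp and Rbm3 were highest in VAT in Foxp3-zero cells. A different mix of classes did not account for all of it, since within naive-like and within Th1-effector-like cells the lowest difference between VAT and SAT was 0.67 ± 0.16, for Cirbp in naive-like cells, against 0.98 over all cells. Tissue temperature and the temperature of handling stay open and were not tested. The chaperone gene Hsph1 and the gene Cacybp, chosen after their values were seen, were higher in SAT than in VAT by 0.65 ± 0.12 and 0.37 ± 0.08.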
